A study of Homo sapiens with 8 samples.

How the data were processed

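RNA was measured in HCT116 cells, an established human colon carcinoma line, on 8 Illumina HumanHT-12 v3 BeadChip arrays in 4 groups of 2. Cells received a non-targeting control siRNA or an siRNA against TAF3, a subunit of the general transcription factor TFIID. From 48 hours after transfection they were left untreated or given 0.5 µM doxorubicin, a topoisomerase poison that breaks DNA, for 24 hours. Per the labels, biotinylated antisense RNA was made from 200 ng of total RNA primed with oligo(dT). Such priming favours RNA with a poly(A) tail. Signals of RNAs that mostly lack such a tail may not reflect their total amount. Among these are replication-dependent histones, RN7SK, SNORD13 and TERC. Groups and replicate numbers came from the sample titles. Untreated arrays carry the numbers 1 and 3 and doxorubicin arrays 2 and 4. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

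The deposited intensity values are linear probe signals, and the submitters' processing notes name BeadStudio without a version. Their further processing is not given in the sources used here. All arrays have the same median signal of 73.9 over 48803 probes, as a single factor per array would give, and the lowest signal of 36.3 shows no background subtraction. A second deposited table holds detection values that its header calls p-values, but they rise with the signal and are therefore 1 minus a detection p-value. Its columns name no sample. The detection p-values were used only as the number of arrays on which a probe was detected, and its 8 signal columns were not used. Each array's background threshold was read from the labelled signals, between the highest signal of probes detected on 0 arrays and the lowest of probes detected on 8 arrays. These bounds lay at most 0.194 signal units apart, and the thresholds ran from 81.4 to 87.4.

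The labelled values have no control probes or detection values, so neqc, the normalization planned first, could not be used. The fallback fixed before the data were examined was taken: normexp background correction with an offset of 50, quantile normalization and log2. Probes with a detection p under 0.05 on at least 2 arrays were kept, which left 20628. Of 48803 probes, 28098 had 1 gene symbol, 13 had several and 20692 were not listed in the gene table. Names were checked through a RefSeq table of GRCh38.p14, in which 28059 probes' gene numbers were found. No build is named for the probes, so no coordinates are given. The brightest kept probe stood for each gene, and a probe without a single symbol stood for itself, giving 16348 features, of which 12250 were named genes.

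Means of the 4 groups were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 4 residual and 4.98 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 16348 features within each of 7 comparisons, called at 0.05. Values written as a ± b are log2 changes with the standard error of that fit, from 2 arrays per group. This standard error pools the spread of all 4 groups, so it can be too small where the groups compared vary more. The median SD was 0.151 untreated and 0.145 with doxorubicin for TAF3 siRNA, and 0.127 and 0.101 for control siRNA. Where every array of a group lay below background, a bound is given: the brighter group's mean against the dim group's mean of, per array, the higher of the background threshold and the probe's own signal. Fixed lists of genes, 31 in number, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation, and fry, which asks whether members move on balance 1 way, were the alternatives. No list call held with an estimated correlation in any of 5 comparisons (4 pairwise and the interaction). With fry, 8 of 11 called lists also passed for doxorubicin with control siRNA, 12 of 15 with TAF3 siRNA, and 0 in the other comparisons. Camera compares members with the other features and fry does not, so fry is more easily passed where many features change.

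Named genes were fixed by rule. TAF3 was always named. For each comparison the rule took the 10 largest increases and 10 largest decreases among called genes whose arrays did not overlap (no such condition for the interaction and the averages). It left out unnamed probes, provisional symbols, pseudogenes and sex-linked markers. Up to 4 members of each described list with the smallest p were added, and a gene named in a comparison may be given its value in the others.

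The fit was tested on simulated data with 16348 features. For doxorubicin with control siRNA, 85 of 100 features changed by 1 log2 unit and 100 of 100 changed by 2 were recovered. For TAF3 siRNA with doxorubicin the numbers were 84 and 99. For the difference between responses they were 21 and 97. False calls numbered 23, 7 and 6 in these comparisons and 32 for doxorubicin averaged over both siRNAs, where all 200 changed features were recovered. In both doxorubicin comparisons the share of false calls was above the nominal 5%. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for input and figures. The alternatives were other inputs, background corrections, scalings, filters, probe summaries and thresholds, fits of 2 groups alone, a replicate block, and leaving out each array in turn. The files give no slide, so a slide block could not be fitted. The small number of arrays limits the precision.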

Results

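Gene expression was compared in HCT116 cells treated with control or TAF3 siRNA, with and without doxorubicin, with 2 arrays in each of 4 groups. The series title asks how TAF3, which binds trimethylated lysine 4 of histone H3, takes part in selective gene activation. Between 17428 and 19533 probes lay above background on each array. The median signal of probes detected on all arrays was 6.02 to 7.24 times that of probes detected on none. The first principal component held 48.3% of the variance and the second 28.0%. The pair of control siRNA doxorubicin arrays agreed most closely (r = 0.994 across features, which are not independent replicates) and the pair of untreated TAF3 siRNA arrays least (r = 0.980).

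The TAF3 transcript itself lay near background. It had 2 probes, of which the first was below background on all 8 arrays. The second was above background only on the control siRNA doxorubicin arrays, with signals of 89.3 and 101.0. Under doxorubicin the mean TAF3 signal was lower with TAF3 siRNA than with control siRNA, but the difference was not called (limma adjusted p = 0.167). Its bound of 1.10-fold takes account of background but not of the spread between arrays. Without doxorubicin both groups lay below background, so no fold is given. Neither the presence nor the size of a knockdown could therefore be shown on these arrays. Effects given below are those of the TAF3 siRNA treatment. Loss of TAF3 and other effects of that siRNA cannot be told apart in this design. CDKN1A, the cell cycle inhibitor p21, rose with doxorubicin by 2.28 ± 0.21 with control siRNA and by 2.23 ± 0.21 with TAF3 siRNA.

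Doxorubicin with control siRNA raised p53 target genes and lowered genes of cholesterol synthesis. The largest increases were TP53I3 (5.08 ± 0.67), a p53-induced quinone oxidoreductase, GALR2 (5.08 ± 0.47), a galanin receptor, H19 (5.03 ± 0.70), an imprinted noncoding RNA, and CBS (4.33 ± 0.48), the transsulfuration enzyme. AKR1B10 (4.12 ± 0.36), LAMP3 (4.10 ± 0.44), TP53INP1 (3.74 ± 0.28) and PRODH (3.45 ± 0.60) also rose. SORCS2 was at least 12.4-fold higher (adjusted p = 0.00163) and PADI4, a peptidylarginine deiminase, at least 10.2-fold higher (adjusted p = 0.000268). The largest decreases were ALDOC (-3.09 ± 0.24), a glycolytic aldolase, MALL (-2.90 ± 0.32), INSIG1 (-2.66 ± 0.30), which holds back sterol synthesis, TERC (-2.51 ± 0.57), the telomerase RNA, and ANKRD37 (-2.49 ± 0.35) and DEPDC1 (-2.21 ± 0.36).

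Of the p53 lists, 27 of 38 measured signalling genes rose (34 adjusted over the list alone), with a median of 1.51 (camera adjusted p = 6.5e-18, and adjusted p = 0.277 with an estimated correlation). Among apoptosis genes 16 of 20 rose (18 adjusted over the list alone), with CDIP1 (2.67 ± 0.26) and PHLDA3 (1.72 ± 0.22) beside TP53INP1 (camera adjusted p = 3.84e-13, and adjusted p = 0.277 with an estimated correlation). Among repair and metabolism genes 19 of 23 rose (19 adjusted over the list alone), among them XPC (1.59 ± 0.16) and ANKRA2 (2.19 ± 0.26) (camera adjusted p = 2.06e-13, and adjusted p = 0.309 with an estimated correlation). Arrest and feedback genes rose in 15 of 19 cases (15 adjusted over the list alone), including PPM1D (2.33 ± 0.24) and SFN (2.18 ± 0.26) (camera adjusted p = 1.64e-09, and adjusted p = 0.32 with an estimated correlation). In the cholesterol synthesis list 14 of 23 genes fell (14 adjusted over the list alone), including SQLE (-2.11 ± 0.22) (camera adjusted p = 3.81e-07, and adjusted p = 0.277 with an estimated correlation). SCD (-2.03 ± 0.21), a fatty acid desaturase placed in that list, fell as well. Of G2/M and mitosis genes 14 of 58 fell (16 adjusted over the list alone), such as CDC20 (-1.44 ± 0.22) and TTK (-1.05 ± 0.17) (camera adjusted p = 1.55e-07, and adjusted p = 0.67 with an estimated correlation). In the glycolysis and hypoxia list 11 of 33 fell (13 adjusted over the list alone), with ALDOC, ANKRD37 and EGLN1 (-1.20 ± 0.16) (camera adjusted p = 0.00154, and adjusted p = 0.502 with an estimated correlation). Ribosome biogenesis genes fell in 11 of 45 cases (18 adjusted over the list alone), including NHP2 (-1.10 ± 0.15) and FBL (-1.01 ± 0.18) (camera adjusted p = 0.00018, and adjusted p = 0.277 with an estimated correlation).

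In all, limma called 2792 features with control siRNA, 1484 higher and 1308 lower (53.2% higher). The share called higher was 64.2% (1498 and 835) on log2 of the deposited signal and 63.2% (1492 and 868) with median centring. The count fell to 971 without control siRNA untreated replicate 1 and to 1297 without replicate 3. It was 268 without control siRNA doxorubicin replicate 2 and 858 without replicate 4, and 4201 in a fit of these 2 groups alone.

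**Figure D1:**
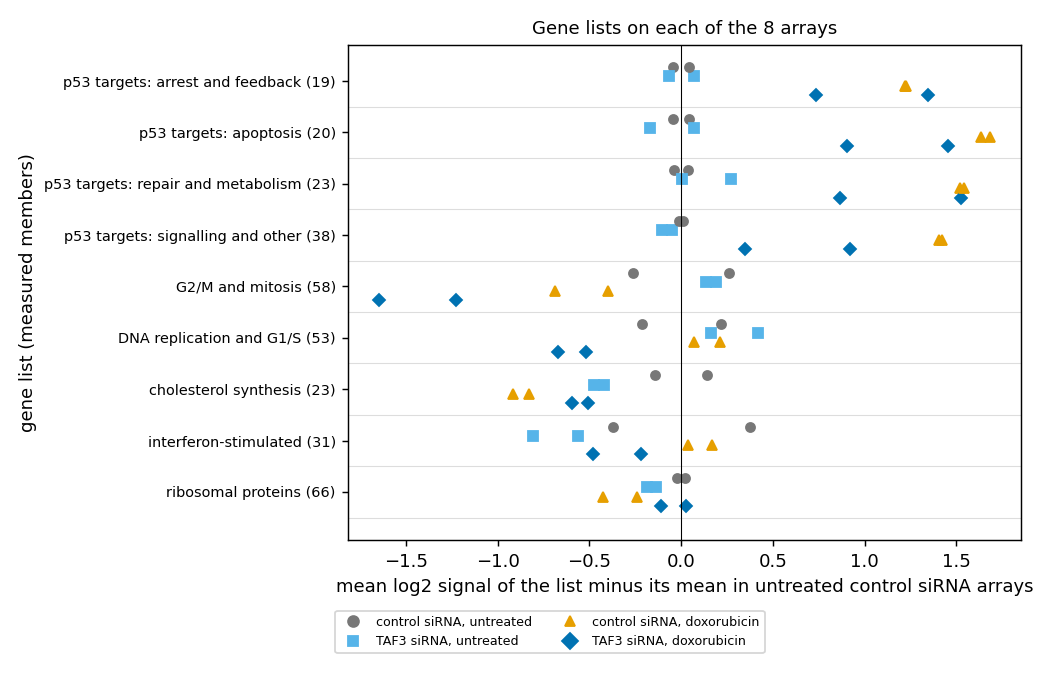
Mean log2 signal of 9 gene lists on each array, minus its mean on the untreated control siRNA arrays (each point is an array, 2 per group). On the doxorubicin arrays the p53 signalling list lies lower with TAF3 siRNA than with control siRNA, as does the G2/M and mitosis list, whose median log2 difference between siRNAs was -0.87.

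With TAF3 siRNA, doxorubicin lowered nearly the whole mitosis list and again raised p53 targets. Of G2/M and mitosis genes 52 of 58 fell (58 adjusted over the list alone), with a median of -1.61 (camera adjusted p = 7.06e-51, and adjusted p = 0.194 with an estimated correlation). The largest decreases were DEPDC1 (-2.52 ± 0.36) and HMMR (-2.50 ± 0.23), CDC20 (-2.40 ± 0.22), an activator of the anaphase-promoting complex, CCNA2 (-2.39 ± 0.21), cyclin A2, and the mitotic kinesin KIF20A (-2.37 ± 0.26). The mitotic kinases NEK2 (-2.31 ± 0.29), BUB1 (-2.11 ± 0.40) and TTK (-2.10 ± 0.17) fell as well. Of DNA replication genes 26 of 53 fell (42 adjusted over the list alone), including ORC1 (-1.58 ± 0.20) and MCM4 (-1.29 ± 0.17) (camera adjusted p = 1.6e-22, and adjusted p = 0.204 with an estimated correlation). Of homologous recombination genes 12 of 26 fell (16 adjusted over the list alone), such as CHEK1 (-1.69 ± 0.22) and BARD1 (-1.01 ± 0.15) (camera adjusted p = 1.77e-12, and adjusted p = 0.194 with an estimated correlation).

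The largest increases with TAF3 siRNA were TP53I3 (3.57 ± 0.67), CXCL8 (3.26 ± 0.59), a neutrophil chemokine, CCN2 (3.22 ± 0.34), connective tissue growth factor, H2BC5 (3.04 ± 0.35), a histone H2B, and SNORD13 (2.95 ± 0.42), TP53INP1 (2.91 ± 0.28), RN7SK (2.87 ± 0.50), ACTA2 (2.56 ± 0.33), GRIN2C (2.47 ± 0.34) and DEPP1 (2.36 ± 0.21). The p53 apoptosis list rose in 12 of 20 genes (16 adjusted over the list alone; camera adjusted p = 8.93e-14, and adjusted p = 0.194 with an estimated correlation). The p53 repair and metabolism list rose in 11 of 23 (17 adjusted over the list alone; camera adjusted p = 7.83e-13, and adjusted p = 0.204 with an estimated correlation). The p53 signalling list rose in 12 of 38 (17 adjusted over the list alone), for example SERPINB5 (1.97 ± 0.34) and CYFIP2 (2.07 ± 0.36) (camera adjusted p = 1.27e-10, and adjusted p = 0.248 with an estimated correlation). The arrest list rose in 9 of 19 (13 adjusted over the list alone), including BTG1 (1.57 ± 0.21) (camera adjusted p = 1.96e-12, and adjusted p = 0.194 with an estimated correlation). Immediate early genes rose in 7 of 28 (11 adjusted over the list alone), including ATF3 (1.98 ± 0.20) and DUSP1 (1.92 ± 0.27) (camera adjusted p = 1.92e-05, and adjusted p = 0.194 with an estimated correlation). Signals of replication-dependent histones rose in 7 of 23 (10 adjusted over the list alone), such as H2AC6 (1.75 ± 0.25) and H2BC21 (1.82 ± 0.29) (camera adjusted p = 2.72e-05, and adjusted p = 0.261 with an estimated correlation). Oligo(dT) priming favours polyadenylated forms, so total histone RNA was not measured.

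With TAF3 siRNA 760 features were called, 339 higher and 421 lower (44.6% higher). The share called higher was 30.3% (203 and 468) on log2 of the deposited signal and 30.1% (212 and 493) with median centring. A fit of these 2 groups alone called 0 features, and the count was 36 without TAF3 siRNA doxorubicin replicate 2, 126 without untreated replicate 3 and 1638 without untreated replicate 1. It was 239 without either control siRNA doxorubicin array. Across features the responses with both siRNAs, which share no array, correlated with r = 0.54 and a covariance of 0.135. Both lists of calls held 212 higher features where independent lists would share 30.8, and 160 lower features where 33.7 would be shared.

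**Figure D2:**
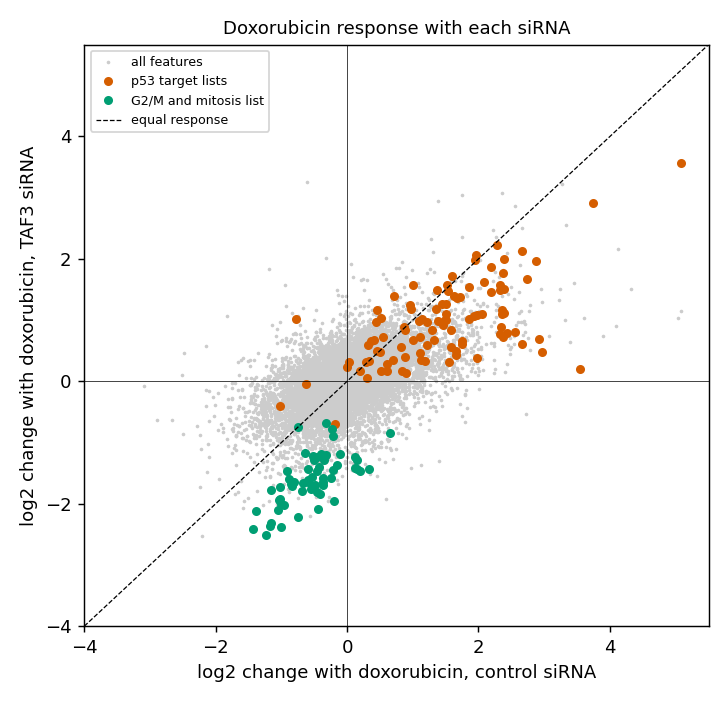
Log2 change with doxorubicin with control siRNA (x axis) and with TAF3 siRNA (y axis) for all 16348 features, with the p53 target lists and the G2/M and mitosis list in colour. The dashed line marks an equal response, and the correlation across features is 0.54.

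TAF3 siRNA without doxorubicin gave no called feature. By limma 0 features passed, 1973 had an unadjusted p under 0.05, and the smallest adjusted p was 0.141. Across features, which are not independent, the TAF3 siRNA effects without and with doxorubicin correlated with r = 0.39. They share no array. Their covariance was 0.0654, and the value of 4.52e-05 simulated with no effect is near 0 by construction. That simulation drew features independently, so it cannot show that the correlation comes from the siRNA. Among interferon-stimulated genes, which answer to antiviral signalling, the median was -0.67, and 11 of 31 were lower adjusted over the list alone (camera adjusted p = 3.14e-11, and adjusted p = 0.561 with an estimated correlation). Its members with the smallest p were UBE2L6 (-0.72 ± 0.18), IFI27 (-1.30 ± 0.33), IFI35 (-0.80 ± 0.21) and IRF9 (-0.96 ± 0.26). The interferon list also differed between the control siRNA untreated arrays, at 0.37 and -0.37 around their mean, against -0.81 and -0.56 with TAF3 siRNA. Cholesterol synthesis genes had a median of -0.40, with 5 of 23 lower adjusted over the list alone, among them EBP (-0.83 ± 0.16) and FDPS (-0.59 ± 0.15) (camera adjusted p = 5.83e-07, and adjusted p = 0.513 with an estimated correlation). DNA replication genes had a median of 0.32, with 4 of 53 higher adjusted over the list alone (camera adjusted p = 1.74e-06, and adjusted p = 0.589 with an estimated correlation). The mean of that list overlapped between siRNAs, at -0.21 and 0.21 on the control arrays and 0.16 and 0.42 with TAF3 siRNA. Glycolysis and hypoxia genes had a median of -0.32, with 7 of 33 lower adjusted over the list alone, such as PFKFB4 (-0.97 ± 0.21) and NDRG1 (-1.10 ± 0.26) (camera adjusted p = 0.000145, and adjusted p = 0.561 with an estimated correlation). The count was 314 (42 higher and 272 lower) without TAF3 siRNA untreated replicate 3, 2 without replicate 1, and 16 without control siRNA untreated replicate 3.

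Under doxorubicin, of 1484 features that doxorubicin had raised with control siRNA, 591 were called lower with TAF3 siRNA and 10 higher. Both comparisons share the control siRNA doxorubicin arrays, which by themselves favour such an opposition. Cell cycle genes also lay lower with TAF3 siRNA. The largest decreases against control siRNA were H19 (-4.06 ± 0.70), PADI4 (-3.31 ± 0.19), KRT80 (-3.16 ± 0.71), SORCS2 (-3.15 ± 0.42), CBS (-3.10 ± 0.48) and LAMP3 (-3.09 ± 0.44), LFNG (-3.28 ± 0.33), a glycosyltransferase that modifies Notch, and SLC4A11 (-2.98 ± 0.43), a membrane transporter. GALR2 also fell (adjusted p = 0.00529). With TAF3 siRNA the PADI4 signal under doxorubicin lay close to background, so the size of its decrease is not exact. The TAF3 siRNA arrays varied widely for H19 (SD 2.0), while both lay below both control arrays. The largest increases were TFPI (2.50 ± 0.34), the tissue factor pathway inhibitor, OR51B4 (2.10 ± 0.17), an olfactory receptor, NEK3 (2.08 ± 0.22), ALDOC (1.91 ± 0.24), PTBP2 (1.89 ± 0.46) and IMMP2L (1.88 ± 0.28), and the transcription factors KLF9 (1.80 ± 0.21) and CREB5 (1.78 ± 0.40). PPA2 rose by 2.15 ± 0.22 on its brightest probe, but another of its probes had the opposite sign.

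Of G2/M and mitosis genes 28 of 58 were lower with TAF3 siRNA (44 adjusted over the list alone), with a median of -0.87 (camera adjusted p = 3.57e-19, and adjusted p = 0.541 with an estimated correlation). That count was 0 without control siRNA doxorubicin replicate 2, 3 without replicate 4 and 8 without TAF3 siRNA doxorubicin replicate 4, with medians of -0.72, -1.01 and -0.99. Among the 28 were CDCA3 (-2.27 ± 0.27), the mitotic transcription factor FOXM1 (-1.53 ± 0.19), and CDK1 (-1.30 ± 0.18). Of DNA replication genes 23 of 53 were lower (28 adjusted over the list alone), led by E2F2 (-1.81 ± 0.17), TK1 (-2.56 ± 0.27) and RRM1 (-1.13 ± 0.16) (camera adjusted p = 4.81e-12, and adjusted p = 0.541 with an estimated correlation). Of p53 signalling genes 15 of 38 were lower (24 adjusted over the list alone), including SLC12A4 (-1.78 ± 0.27) and SPHK1 (-1.46 ± 0.25) (camera adjusted p = 7.49e-08, and adjusted p = 0.541 with an estimated correlation). Of p53 apoptosis genes 4 of 20 were lower (4 adjusted over the list alone), including CDIP1 (-2.09 ± 0.26) and SCN3B (-1.11 ± 0.19) (camera adjusted p = 0.0301, and adjusted p = 0.541 with an estimated correlation). Of the interferon list 4 of 31 were lower (4 adjusted over the list alone), with OAS3 (-1.73 ± 0.25) and ISG15 (-1.56 ± 0.40) (camera adjusted p = 0.0058, and adjusted p = 0.728 with an estimated correlation). Of the TFIID subunits other than TAF3 2 of 14 were higher (4 adjusted over the list alone), TAF5 (0.94 ± 0.26) and TAF13 (0.62 ± 0.16) (camera adjusted p = 0.0366, and adjusted p = 0.541 with an estimated correlation). Neither TAF5 nor TAF13 was called on log2 of the deposited signal or with median centring. Ribosomal protein genes were higher in 14 of 66 cases and lower in 1 (15 and 1 adjusted over the list alone), with RPL13A (1.12 ± 0.17), RPL7 (0.94 ± 0.16) and RPL4 (1.07 ± 0.18) (camera adjusted p = 0.000649, and adjusted p = 0.541 with an estimated correlation). Immediate early genes were higher in 6 of 28 (10 adjusted over the list alone), including DUSP1 (1.48 ± 0.27) and EGR1 (1.39 ± 0.32) (camera adjusted p = 0.00855, and adjusted p = 0.541 with an estimated correlation).

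Under doxorubicin, limma called 2257 features between siRNAs, 1067 higher and 1190 lower with TAF3 siRNA (47.3% higher). The share called higher was 39.0% (638 and 997) on log2 of the deposited signal, 38.6% (640 and 1018) with median centring and 31.6% (299 and 648) among changes of at least 2-fold. The count was 3 without control siRNA doxorubicin replicate 2, 104 without replicate 4 and 155 without TAF3 siRNA doxorubicin replicate 4. Only 3 features, of which PADI4 alone is named above, were called whichever of the 8 arrays was left out. Effects of doxorubicin with control siRNA and of TAF3 siRNA with doxorubicin share the control siRNA doxorubicin arrays, which alone gave a simulated correlation of -0.50. The observed correlation was -0.58 and the covariance -0.174, against -0.0219 simulated. Features were simulated as independent, which limits that comparison. Of features called higher with doxorubicin, 591 were called lower with TAF3 siRNA, where independent lists would share 108. Of features called lower with doxorubicin, 385 were called higher with TAF3 siRNA, where 85.4 would be shared. Part of that excess may come from the shared arrays.

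**Figure D3:**
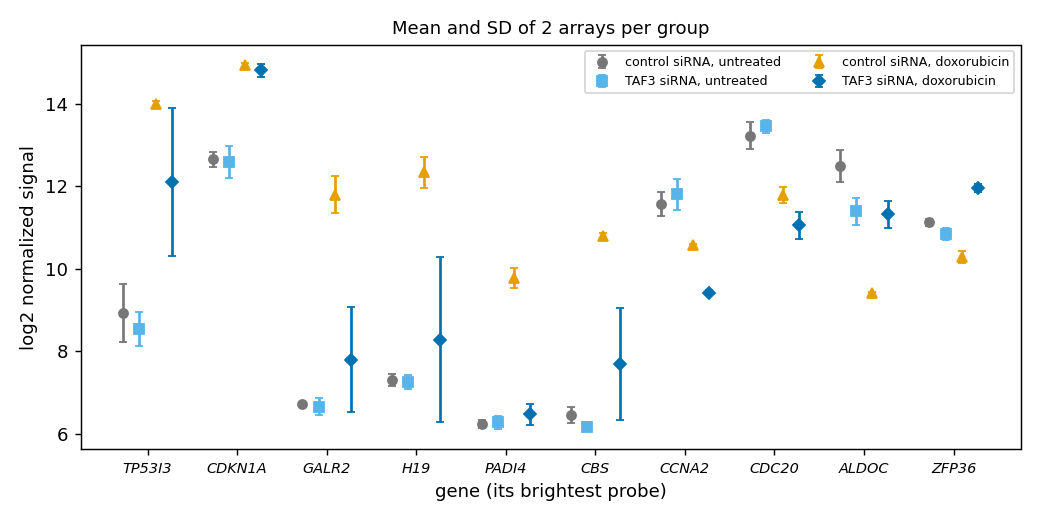
Mean log2 normalized signal of 10 genes in each group, with the SD of 2 arrays as error bars. With doxorubicin PADI4 stood at 9.78 with control siRNA and 6.46 with TAF3 siRNA, the latter close to background, while CDKN1A rose with both siRNAs.

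The doxorubicin response itself differed between siRNAs for 6 features by the interaction test, with 2424 at an unadjusted p under 0.05. PADI4 responded less with TAF3 siRNA (adjusted p = 0.00883), with no size given because both untreated groups lay below background. GCHFR (-1.69 ± 0.20), a regulator of tetrahydrobiopterin synthesis, and 2 probes with no gene symbol also responded less. ALDOC, which fell with control siRNA, had an interaction of 3.01 ± 0.34 (adjusted p = 0.0471). ZFP36, which destabilises inflammatory messenger RNAs, had an interaction of 1.95 ± 0.23 (adjusted p = 0.0471). The count was 1 on log2 of the deposited signal and with median centring, 0 with detection on all 8 arrays, 22 without the detection filter and 90 with a trended robust fit. Leaving out an array gave 0 to 324 calls, with 324 without TAF3 siRNA doxorubicin replicate 2 and 252 without TAF3 siRNA untreated replicate 1. The other 6 arrays gave 0 or 1, and no feature was called throughout.

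Whether the response as a whole was smaller with TAF3 siRNA was asked over features selected on the mean of both responses, which does not favour a direction. Over 1824 features higher with doxorubicin, the median log2 change was 0.84 with control siRNA and 0.54 with TAF3 siRNA, and 74.8% responded less with TAF3 siRNA. The median interaction of -0.33 did not pass (camera p = 0.121 with an estimated correlation), but it was -0.53 and passed without TAF3 siRNA doxorubicin replicate 2 (camera p = 0.0226 with an estimated correlation). It was -0.17 without TAF3 siRNA doxorubicin replicate 4 and -0.0799 without TAF3 siRNA untreated replicate 1. Over 1794 lower features the medians were -0.71 and -0.54, with 63.9% responding less (camera p = 0.390 with an estimated correlation). Their median interaction of 0.18 turned to -0.0516 without TAF3 siRNA untreated replicate 1. Features were selected anew in each fit without an array, where the groups were unbalanced and the selection can favour a direction.

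Averaged over both siRNAs, doxorubicin changed 3618 features, 1824 higher and 1794 lower. The largest changes included TP53I3 (4.32 ± 0.48), CCN2 (3.25 ± 0.24) and RN7SK (2.71 ± 0.35), the last a noncoding RNA that restrains transcription elongation, and MIX23 (-1.98 ± 0.16), RAB26 (-1.77 ± 0.21) and CFD (-1.77 ± 0.33). The count was 1537 without control siRNA doxorubicin replicate 2, 2028 without replicate 4 and 2231 without TAF3 siRNA doxorubicin replicate 2, and 1429 features were called whichever array was left out. Averaged over both treatments, TAF3 siRNA changed 1877 features, 895 higher and 982 lower (47.7% higher). The share called higher was 58.5% (821 and 582) on log2 of the deposited signal and 57.2% (806 and 603) with median centring, but 14.7% (38 and 220) among changes of at least 2-fold. ZBED2 (-2.15 ± 0.16) and HCFC1R1 (-2.09 ± 0.25), the interferon-induced IFI6 (-1.88 ± 0.42) and the antigen-presenting HLA-B (-1.78 ± 0.25) fell, and TAF5 (1.22 ± 0.19), another TFIID subunit, and SEC62 (1.26 ± 0.20) rose. That count was 1 (ZBED2) without control siRNA doxorubicin replicate 2, 3 without replicate 4, 312 without TAF3 siRNA doxorubicin replicate 4, 172 and 669 without control siRNA untreated replicates 1 and 3, and 924 and 3049 without TAF3 siRNA untreated replicates 1 and 3.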

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

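The tests of spread, labels, knockdown, p53 lists, scaling and single arrays as explanations, and of splits with treatment in the fit, were chosen after results had been seen, while the interaction, the leave-one-out and scaling fits they draw on and the counts over 35 splits were planned.

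The doxorubicin response differed between siRNAs for 6 features. The interactions were 3.01 for ALDOC, 1.95 for ZFP36, -1.69 for GCHFR, -3.35 for PADI4, and -1.84 and -1.78 for 2 probes with no gene symbol. The values for PADI4 and for the probe at -1.78 are not exact sizes, because both untreated groups lay below background. Of the fixed lists, 12 differed at the preset correlation. Median interactions were -1.04 for G2/M and mitosis, -1.10 for DNA replication and G1/S, -0.74 for homologous recombination, -0.66 for p53 signalling, -0.40 for p53 repair and metabolism and -0.21 for p53 apoptosis. They were 0.68 for cholesterol synthesis, 0.47 for replication-dependent histones, 0.44 for ribosomal proteins, 0.43 for immediate early genes, 0.26 for NF-kB and inflammation and 0.20 for glycolysis and hypoxia. None of the 12 held with an estimated correlation (smallest adjusted p = 0.345).

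TAF3 siRNA without doxorubicin gave 0 called features, and its arrays agreed least. Leaving out replicate 3 gave 314 calls and leaving out replicate 1 gave 2, so the spread within this group may account for the lack of calls. Unequal knockdown could not be tested, because 0 TAF3 readings lay above background on the 4 untreated arrays. A wrong label on replicate 3 also stays open. Over the 2257 features called under doxorubicin, that array moved by 0.0939 on average in the direction of the effect. Replicate 1 moved by 0.345, with 0.0326 between the control arrays. Of 31 interferon genes, 22 lay below both control arrays in replicate 3 and 24 in replicate 1. Over all features TAF3 siRNA replicate 3 lay nearest to control replicate 3, with a root mean square log2 difference of 0.312. Its difference was 0.391 from control replicate 1 and 0.403 from its own replicate, with 0.318 between the controls. On the second principal component it stood at 18.8, the controls at 24.0 and 22.9 and TAF3 siRNA replicate 1 at -16.4. The first component went the other way, with this array at -28.6, TAF3 siRNA replicate 1 at -31.1 and the controls at -19.8 and -22.1.

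The p53 signalling list had a median interaction of -0.66 at the preset correlation, with adjusted p = 0.438 with an estimated correlation, adjusted p = 0.193 with fry and 1 of 38 members called. Several values go against a uniformly weaker response, but it stays open. The list kept 64.4% of its control response on replicate 2 and 25.3% on replicate 4, where the other p53 genes kept 87.5% and 46.4% (larger permutation p = 0.00214, two-sided, over genes, which are not independent). Against the spread between arrays it lay -0.36 ± 0.07 from the common share. Neither value decides, because the list was picked of 4 as the one that kept least, and both arrays share the same untreated baseline. The mitosis list fell further with TAF3 siRNA, by -1.06 ± 0.36 (standard error from the spread between arrays), which a weaker response would not give, but this list too was picked after its value was seen and the difference had adjusted p = 0.406 with an estimated correlation. Replicate 4 alone stays open as well. Without it the list differed by -0.496 ± 0.249 from control siRNA under doxorubicin, a standard error from the spread between arrays pooled over the groups, which does not separate it from 0 at 4 degrees of freedom. Over all features TAF3 siRNA doxorubicin replicate 4 lay nearer to the untreated arrays on the first principal component than the other doxorubicin arrays did. It stood at -12.8, replicate 2 at 17.9, the control siRNA doxorubicin arrays at 52.1 and 44.4, and the untreated arrays between -31.1 and -19.8. Its root mean square log2 difference was 0.382 from TAF3 siRNA untreated replicate 1 and 0.359 from TAF3 siRNA doxorubicin replicate 2. The p53 arrest list mean, relative to untreated control siRNA, stood at 0.73 on replicate 4 and 1.34 on replicate 2. The control siRNA doxorubicin arrays stood at 1.22 and 1.23. The p53 repair list stood at 0.87 and 1.53, against 1.52 and 1.54. For these lists only replicate 4 lay below both control arrays. The p53 apoptosis and signalling lists lay below them on both replicates. No biological explanation is put forward while these explanations are open.

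Under doxorubicin 28 of 58 mitosis genes and 23 of 53 DNA replication genes were called lower with TAF3 siRNA. The count of mitosis genes was 0 without control siRNA doxorubicin replicate 2, 3 without replicate 4, 19 without TAF3 siRNA doxorubicin replicate 2 and 8 without replicate 4, with medians from -1.01 to -0.700 against -0.866 over all arrays. Both lists passed camera only at the preset correlation (adjusted p = 0.541 for both with an estimated correlation and 0.0901 for both with fry). Scaling was argued against in part, since the median change of the mitosis list was -0.948 with median centring and -0.952 on log2 of the deposited signal. The deposited arrays already had equal medians, so these are nearly the same check. That median lay below background, so neither aligned the arrays on expressed probes. A single array stays open. The difference of the list mean nearest to 0 was -0.685 ± 0.316, without TAF3 siRNA doxorubicin replicate 2, which the spread between arrays does not separate from 0, and the largest was -1.10. The number of cycling cells was not measured.

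Other splits of the arrays bear on the averaged effects. In fits of 2 groups alone, the real doxorubicin split called 1513 features and the highest of the other 34 called 0. So 1 of 35 splits gave as many, the smallest share that 35 splits can give. The other splits leave the doxorubicin effect in the spread, which keeps their counts low. Arrays of a group may also be technical replicates, so chance is not excluded. The real TAF3 split called 0 in a fit of 2 groups alone, where the doxorubicin effect stays in the spread. All 35 splits therefore necessarily gave as many (the highest other was 1513), and this count decides nothing. With treatment in the fit, an added test, the real TAF3 split called 368 and the highest other 0, with 1 of 18 splits giving as many, which are too few for a share under 0.05.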

How the results depend on the processing

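Leave-one-out fits of gene lists and the offset of 16 were chosen after seeing the data. The planned change of the neqc offset could not be run, nor could a slide block. In leave-one-out fits the lone array of a group is assumed to vary like the other groups. Signal limits TAF3 itself, which was below or near background. Leaving out each array in turn gave 268 to 3423 features for doxorubicin with control siRNA, 36 to 1638 with TAF3 siRNA, 0 to 314 for TAF3 siRNA without doxorubicin, 3 to 3027 with doxorubicin, 0 to 324 for the difference between responses, 1537 to 3996 for the averaged doxorubicin effect and 1 to 3049 for the averaged TAF3 effect. A lone array also removes a residual degree of freedom, and no further cause was tested. Fits of 2 groups alone gave 4201 and 0 for doxorubicin with control and TAF3 siRNA. Requiring a 2-fold change left, by construction, 1187 (729 higher) and 432 (190 higher) for these, 947 (299 higher) for TAF3 siRNA with doxorubicin, 653 (414 higher) for averaged doxorubicin and 258 (38 higher) for averaged TAF3 siRNA. For the difference between responses, counts were 1 on log2 of the deposited signal, 1 with median centring, 22 without the detection filter, 0 with detection on all 8 arrays (where fewer features are tested) and 90 with a trended robust fit, and the cause was not tested. The median interaction ran from -0.53 to -0.0799 over higher features and from -0.0516 to 0.31 over lower features when an array was left out. Features were selected anew in each of these unbalanced fits, which can favour a direction. Selecting features with control siRNA alone gave -0.62 and 0.54, and with TAF3 siRNA alone 0.16 and -0.57, as selection on a single arm favours that arm.

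The labels give same-numbered arrays only a number in common, and their deviations from the group means correlated with r = -0.03 without and 0.21 with doxorubicin. With a replicate block the TAF3 siRNA counts were 0, 2361 and 1984 without doxorubicin, with it and averaged, and the difference between responses gave 2, of which 1 was among the 6. Over 432 named gene results, 6326 values kept their side of the threshold, 979 lost it and 79 gained it, and none reversed. Of 58 list calls, 58 were lost with an estimated correlation and 38 with fry. Over the leave-one-out fits, the adjusted p of the list change with TAF3 siRNA without doxorubicin ran from 1.83e-09 to 0.269 for mitosis and from 2.95e-05 to 0.994 for histones, and both turned direction without control siRNA untreated replicate 1. In all, 20 of the 58 list calls were lost without some array. Among these the highest adjusted p was 0.112 for DNA replication without doxorubicin, 0.146 for p53 apoptosis, 0.111 for TFIID subunits and 0.0572 for immediate early genes with TAF3 siRNA and doxorubicin, and 0.587 for p53 repair and 0.368 for p53 apoptosis in the difference between responses.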

Other observations

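Some genes outside the lists described above also moved with doxorubicin with control siRNA. The mesenchymal transcription factor SNAI2 was at least 4.47-fold higher (adjusted p = 0.00153), and smooth muscle actin ACTA2 (3.32 ± 0.33) rose, while TWIST1 (-0.67 ± 0.15) fell. The list of 9 mesenchymal genes did not pass camera but passed fry (2 higher and 1 lower, 3 and 1 adjusted over the list alone, camera adjusted p = 0.497, fry adjusted p = 0.0233). Of 9 skeletal muscle genes 3 were higher and 1 lower, the same numbers as adjusted over the list alone, and the list passed fry but not camera (camera adjusted p = 0.102, fry adjusted p = 0.0221). TNNT1 (-0.85 ± 0.16) fell, CKM, muscle creatine kinase, was at least 1.96-fold higher and TNNI2, a troponin, at least 2.09-fold higher, and under doxorubicin both were lower with TAF3 siRNA, by at least 1.94-fold and 2.07-fold. The collagen gene COL5A1 was at least 2.21-fold higher with doxorubicin. No marker list of fibroblasts, blood, endothelium or hepatocytes passed camera in any of 5 comparisons (smallest adjusted p = 0.0728). With fry the fibroblast list passed for doxorubicin with control siRNA (2 of 4 higher, 2 adjusted over the list alone, fry adjusted p = 0.0140). Autophagy and lysosome genes rose in 6 of 26 cases with control siRNA (12 adjusted over the list alone), such as PSAP (0.93 ± 0.15), CTSB (1.12 ± 0.21) and ULK1 (1.25 ± 0.25) (camera adjusted p = 0.000946, and adjusted p = 0.277 with an estimated correlation).

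Of 12 genes often used as references, 2 fell with doxorubicin and TAF3 siRNA, TUBB (-1.91 ± 0.31) and HPRT1 (-1.08 ± 0.16), and 10 were not called (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.109, fry adjusted p = 0.0354). Under doxorubicin 1 of 12, GUSB, was lower with TAF3 siRNA (-2.18 ± 0.39; 2 lower adjusted over the list alone, camera adjusted p = 0.212).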
